A study of Oncorhynchus mykiss with 9 samples.

How the data were processed

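Gill RNA of rainbow trout was sequenced in 9 libraries, 3 for each of 3 groups: control, moderate hypoxia and severe hypoxia. Samples were grouped by their labels, which give the oxygen level and the sampling time of each group. The count values were deposited by the authors as whole numbers of reads per gene, not normalised, per the file headers. The authors also deposited FPKM values per library and their mean per group, per the file headers; these were not used for tests here. The log2 fold change in the authors' deposited tables is the log2 ratio of the group means of FPKM, per the file headers and values. The p-value and FDR columns come from the authors' comparisons, per the file headers, and the test behind them is not given in the sources used here. Bowtie2 2.2.8 and HISAT2 are named, per the submitters' processing notes, without their roles; the counting tool, genome build and annotation are not given in the sources used here. Each comparison came as a table of all 44167 genes and a table of called genes of 487, 576 and 158 genes. Broken lines that held no gene were dropped, 76, 38 and 38 in the full tables and 1, 3 and 0 in the tables of called genes.

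Genes carry NCBI gene numbers or the numbers of assembled loci, and both are printed as the files give them. All 41897 NCBI numbers matched the RefSeq gene table of assembly USDA_OmykA_1.1, which was used for names only. A symbol was lacking for 6672 genes, and 4062 genes had 0 counts in every library. Reads of near-identical copies, as among immunoglobulin loci, mucins and chemokines or among copies from the salmonid genome duplication, can be split by the authors' counting in a way the tables do not show, so values of single copies are uncertain. Total counts ran from 13364129 to 17738766 per library. The floor for a value of 0 was 3 counts, and floors cover counting error only.

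Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 30581 genes, and libraries were scaled by TMM. One fit covered all 9 libraries with a mean per group and 6 residual degrees of freedom. Each of the 3 comparisons was tested by the robust quasi-likelihood F test of edgeR with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Levels are TMM-scaled CPM given as mean ± SD of 3 libraries, and changes are log2 fold changes ± SE.

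The lists, the named gene rule, the tests and the alternatives, apart from those named below as later, were chosen before the data were examined. A pair of description entries was shortened later, which changed the members of no list. The 30 lists were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, two-sided, with adjustment over the 30 lists of a comparison. They cover HIF targets, glycolysis, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, fatty acid and sterol synthesis, gluconeogenesis and glycogen, inflammation, interferon-stimulated genes, complement and coagulation, antigen presentation, T cell, B cell, myeloid, red blood cell, ionocyte, epithelial, endothelial and muscle markers, heat shock, the integrated stress response, antioxidants, apoptosis, autophagy, cell cycle, ribosomal proteins, the clock, glucocorticoid-responsive genes, immediate-early genes and extracellular matrix. A gene joined a list by its symbol or by the start of its description, and each paralog counted as a gene. Intervals of list medians are 95% bootstrap intervals over members from 2000 draws, so they cover the spread between members and not that between libraries.

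The named genes followed a rule. In each comparison they were the 6 largest rises and 6 largest falls among called genes with a symbol or description, groups that did not overlap and at least 1 CPM in the higher group, with genes of the same description counted once. For each list that was called or had at least 3 called members, the 2 members with the smallest adjusted p per direction were added. The best-expressed copies of hif1a, egln3, vegfa, ldha, hsp70, il1b, tnf, per2 and alas2 were always included. The text names fewer where a list is only summarised.

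The tests were tested on simulated counts for 30581 genes, 200 of them changed. At a 2-fold change edgeR recovered 63% of changed genes for moderate hypoxia against control, 67% for severe hypoxia against control and 63% for severe against moderate hypoxia. At a 4-fold change it recovered 80%, 84% and 86%, and 5.9%, 7.4% and 8.6% of its calls were false. False calls made up 12.9%, 15% and 19.4% with DESeq2 and 6.8%, 5.3% and 8.7% with limma-voom. A list raised 1.5-fold was called in each comparison, with 0 of 29 other lists. The simulated genes were drawn independently, so this cannot show how often lists of correlated genes are called falsely.

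The alternatives were DESeq2 size factors, upper quartile scaling, no filter, a stricter filter (1 CPM in 3 libraries and a mean count of 10), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, each library left out in turn, hemoglobin genes removed, a test against a 2-fold change, camera with an estimated correlation, fry, membership by symbol alone and genes of at least 10 CPM. Alternatives for FPKM alone did not apply. After the data were seen, the library of largest hemoglobin share was left out of each group, and the kinases were left out of the ribosomal protein list. Pathways of the deposited KEGG annotation with at least 10 measured genes were tested by the one-sided Fisher's exact test, also chosen after the data were seen. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.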

Results

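Gill transcripts of rainbow trout (Oncorhynchus mykiss) were measured by RNA sequencing in 9 libraries from fish of about 130 g held at 12 °C. The control group had 3 libraries from normoxic water with 8.5 mg/L dissolved oxygen, taken at 0 h. The moderate hypoxia group had 3 libraries from fish kept for 12 h at 4.5 mg/L, and the severe hypoxia group had 3 libraries from fish kept for 12 h at 3.0 mg/L, each level held within 0.1 mg/L. Both comparisons with the control therefore also compared 2 sampling times, while severe and moderate hypoxia were sampled at the same time. The labels do not say that the libraries of a group came from separate fish, so p-values measure the spread between these samples. They also name no tanks, so a tank difference between groups, severe against moderate included, cannot be told apart from an effect of oxygen.

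The deposited tables listed 44167 genes, 41897 with an NCBI gene number and 2270 assembled loci. Total counts per library ran from 13364129 to 17738766, and 3 counts, the floor used for a value of 0, corresponded to 0.169 to 0.224 CPM in a library. The top gene in every library was COX1, the mitochondrial cytochrome c oxidase subunit 1, with 1.23% to 1.48% of counts. Hemoglobin genes took 1.333% of counts in control replicate 3, 1.229% in moderate replicate 2 and 1.312% in severe replicate 2, against 0.5% to 0.675% in the other libraries. On the first principal component (25.1% of the variance), control libraries lay between -51.7 and -44 and hypoxia libraries between 16 and 36.3. Severe replicate 3 stood apart on the second component (15.9%), at 59.1 against 14.6 and -1.4 for the other severe libraries. Replicates within a group differed by more than sampling noise in every pair, with a chi-square per gene of 8.35 to 21.07.

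After 12 h of moderate hypoxia, camera with a preset correlation called 13 of 30 lists, among them HIF targets, inflammatory and glucocorticoid-responsive genes (higher) and cell cycle genes (lower). With an estimated correlation only the inflammatory list was called. Egln3 (110505778), a prolyl hydroxylase that marks hypoxia-inducible factor (HIF) for degradation, rose 3.46-fold, from 4.22 ± 1.24 to 14.5 ± 0.734 CPM (SD, n = 3). The cytokine gene il1b (100136024) rose from 3.1 ± 0.875 to 21.9 ± 5.31 CPM, and a C-C motif chemokine 20-like gene (110531007) rose from 10.8 ± 3.43 to 223 ± 61 CPM. The largest fall was that of semaphorin Sema3f (110527789), from 30.5 ± 4.47 to 1.55 ± 0.373 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1515 of 30581 genes passed an adjusted p of 0.05, 1000 higher and 515 lower in moderate hypoxia. Of these, 401 changed at least 2-fold in the estimate (289 higher, 112 lower), and 63 passed a test against a 2-fold change (57 higher, 6 lower). The values of the groups did not overlap for 8080 genes (26.4%), where chance gives 10%.

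The list of HIF pathway and hypoxia targets rose in moderate hypoxia (camera adjusted p = 5e-04; adjusted p = 0.15 with an estimated correlation). Of its 59 measured members 10 rose, 1 fell and 48 did not pass; adjusted over the list alone, 17 rose and 2 fell. Besides Egln3, ero1a (110505225), an oxidase of disulfide formation in the endoplasmic reticulum, rose by 1.35 ± 0.15 on the log2 scale (SE), and hif1a (100135944), the oxygen-regulated HIF subunit, by 0.45 ± 0.10, a call that held in 14 of 19 alternative settings. Another copy of hif1a (110505629), named after its values were seen, rose by 0.68 ± 0.11. The member that fell was ANGPTL4 (110530122), an inhibitor of lipoprotein lipase, at -0.66 ± 0.13. The growth factor gene VEGFA (110504679) was at 14.3 ± 1.85 CPM against 12.9 ± 0.39 in the control (edgeR adjusted p = 0.69), and ldha (110490604) was at 0.787 ± 0.304 against 0.506 ± 0.0332 CPM (0.63). The glycolysis list rose (camera adjusted p = 0.0088; adjusted p = 0.19 with an estimated correlation) with 5 of 83 members higher and 1 lower, or 6 and 1 adjusted over the list alone. Phosphoglycerate mutase pgam1b (110493407) rose by 0.79 ± 0.12 and hexokinase HK1 (110499407) by 0.58 ± 0.09. The fatty acid oxidation list fell (camera adjusted p = 0.0088; adjusted p = 0.49 with an estimated correlation), although only HADH (110497327) of its 39 members passed, by test over all genes and over the list alone, in 14 of 19 settings. That call was lost without moderate replicate 2 (camera adjusted p = 0.053) and without the library of largest hemoglobin share in each group (0.091), a setting chosen after seeing the shares.

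Inflammatory cytokines, chemokines and NF-kappa B feedback genes rose as a list (camera adjusted p = 5.6e-05), a call that also held with an estimated correlation (adjusted p = 0.037). Of 176 measured members 30 rose, 3 fell and 143 did not pass; adjusted over the list alone, 43 rose and 6 fell. A C-C motif chemokine 19 gene (110536449), whose product attracts lymphocytes and dendritic cells, rose by 1.85 ± 0.13, the NF-kappa B inhibitor NFKBIA (110497729) by 1.23 ± 0.10, and tnf (100136064) by 1.65 ± 0.36 in 14 of 19 settings. The members that fell were a C-X-C motif chemokine 11 gene (110485790, in 12 of 19 settings), the inhibitor NFKBIZ (110527232) and the receptor il1rl1 (101268979). The cytokine gene il17c2 (100462682) had no count in the control and 82 counts in moderate hypoxia, at 0.527, 2.62 and 2.29 CPM in replicates 1, 2 and 3. Its pooled level in moderate hypoxia was 27-fold that of a floor of 3 counts over the control group. T cell markers rose (camera adjusted p = 0.001; adjusted p = 0.19 with an estimated correlation), with 4 of 81 members higher and 2 lower, or 11 and 3 adjusted over the list alone. A CD4 gene (110489493) rose by 0.50 ± 0.09, while the cytotoxic effector perforin Prf1 (110488267) fell from 86.5 ± 17.8 to 44.7 ± 3.89 CPM. In the myeloid list 6 members rose and 5 fell (camera adjusted p = 0.15). CYBB (110504932), the catalytic subunit of the phagocyte NADPH oxidase, rose from 93.2 ± 4.74 to 613 ± 107 CPM, and the gene with the symbol MPO, described as eosinophil peroxidase (110509901), fell from 1470 ± 88.4 to 948 ± 74.4 CPM.

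Cell cycle and DNA replication genes fell (camera adjusted p = 9.8e-12; adjusted p = 0.19 with an estimated correlation). No member rose, 16 of 112 fell and 96 did not pass; adjusted over the list alone, 27 fell. The flap endonuclease fen1 (110535235) fell by 0.76 on the log2 scale and the replication licensing factor mcm2 (110528595) by 0.82. Antioxidant and NRF2 genes fell (camera adjusted p = 0.003; adjusted p = 0.19 with an estimated correlation), with 1 of 97 members higher and 8 lower, or 3 and 11 adjusted over the list alone, among them a gene of the glutathione transferase MGST1 (118942842) at -0.99 ± 0.11. Cytosolic ribosomal proteins fell as a list (camera adjusted p = 3.8e-05; adjusted p = 0.61 with an estimated correlation) by a median of 0.12 on the log2 scale. The 1 member of 212 that passed over all genes, and that rose, in 11 of 19 settings, was RPS6KA3 (110516493), a kinase and not a ribosomal protein. Over the list alone 0 passed. Extracellular matrix genes fell (camera adjusted p = 0.0045; adjusted p = 0.61 with an estimated correlation), with 8 of 226 lower and 1 higher, or 6 and 1 adjusted over the list alone, among them laminin lama5 (110492700) at -1.23 ± 0.16. The extracellular matrix call was lost without control replicate 1 (camera adjusted p = 0.13) or moderate replicate 1 (0.44).

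Glucocorticoid-responsive genes rose in moderate hypoxia (camera adjusted p = 1e-04; adjusted p = 0.19 with an estimated correlation). Of 60 members 13 rose and 2 fell, or 18 and 2 adjusted over the list alone; 16 of the 60 are also in another list. The transcription factor klf9 (110525414) rose from 2.45 ± 0.685 to 15 ± 1.13 CPM and the receptor co-chaperone fkbp5 (110528325) from 6.41 ± 0.499 to 22.5 ± 6.16 CPM. The members that fell were 2 genes of hsd11b2, the enzyme that inactivates cortisol (100135822 and 118944412), in 13 and 12 of 19 settings. Circadian clock genes rose (camera adjusted p = 0.0088; adjusted p = 0.19 with an estimated correlation), with 12 of 79 higher and 5 lower, or 20 and 7 adjusted over the list alone. Tef (110538372) rose by 1.43 ± 0.14 and NR1D2 (110515629) by 1.31 ± 0.14, both transcription factors of the clock, and PER2 (110508801) stood at 4.95 ± 0.606 CPM against 2.81 ± 0.854 (edgeR adjusted p = 0.079). Autophagy genes rose (camera adjusted p = 0.0067; adjusted p = 0.22 with an estimated correlation), 8 members higher, 1 lower and 96 not past the test, or 9 and 1 adjusted over the list alone. The receptor sqstm1 (110505107) rose by 0.48 ± 0.10 in 15 of 19 settings, and tfeb (110528026), a transcription factor that promotes autophagy, was the member that fell, in 12 of 19 settings.

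Ionocyte and ion transport genes rose (camera adjusted p = 0.0074; adjusted p = 0.19 with an estimated correlation), 5 of 88 higher and 2 lower, or 9 and 3 adjusted over the list alone. The bicarbonate cotransporter SLC4A4 (110509568) rose from 37.9 ± 2.44 to 92.2 ± 5.36 CPM, and a carbonic anhydrase 4 gene with the symbol CA12 (110530651) from 201 ± 23.2 to 429 ± 14.5 CPM. The members that fell were ammonia channels, rhcg (100136259), from 373 ± 69.9 to 183 ± 15.7 CPM, and rhbg2a (100191034), the latter in 14 of 19 settings. In the epithelial and mucous list, which was not called (camera adjusted p = 0.068), 22 of 167 members rose and 11 fell, or 25 and 15 adjusted over the list alone. A mucin-5ac-like gene (118940990) rose by 3.25 ± 0.29 and keratin krt8 (110528490) fell by 0.80 on the log2 scale. An assembled filaggrin-like locus (15049) rose from 6.74 ± 4.46 to 107 ± 14.8 CPM and MFAP4 (110491216) from 1.08 ± 0.478 to 16 ± 3.8 CPM. Leaving out 1 library moved the count of 1515 calls by over 1.5 times without control replicate 1 (849), 2 (935) or 3 (934) and without moderate replicate 1 (930) or 3 (957). Without the library of largest hemoglobin share in each group 730 genes were called.

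**Figure D1:**
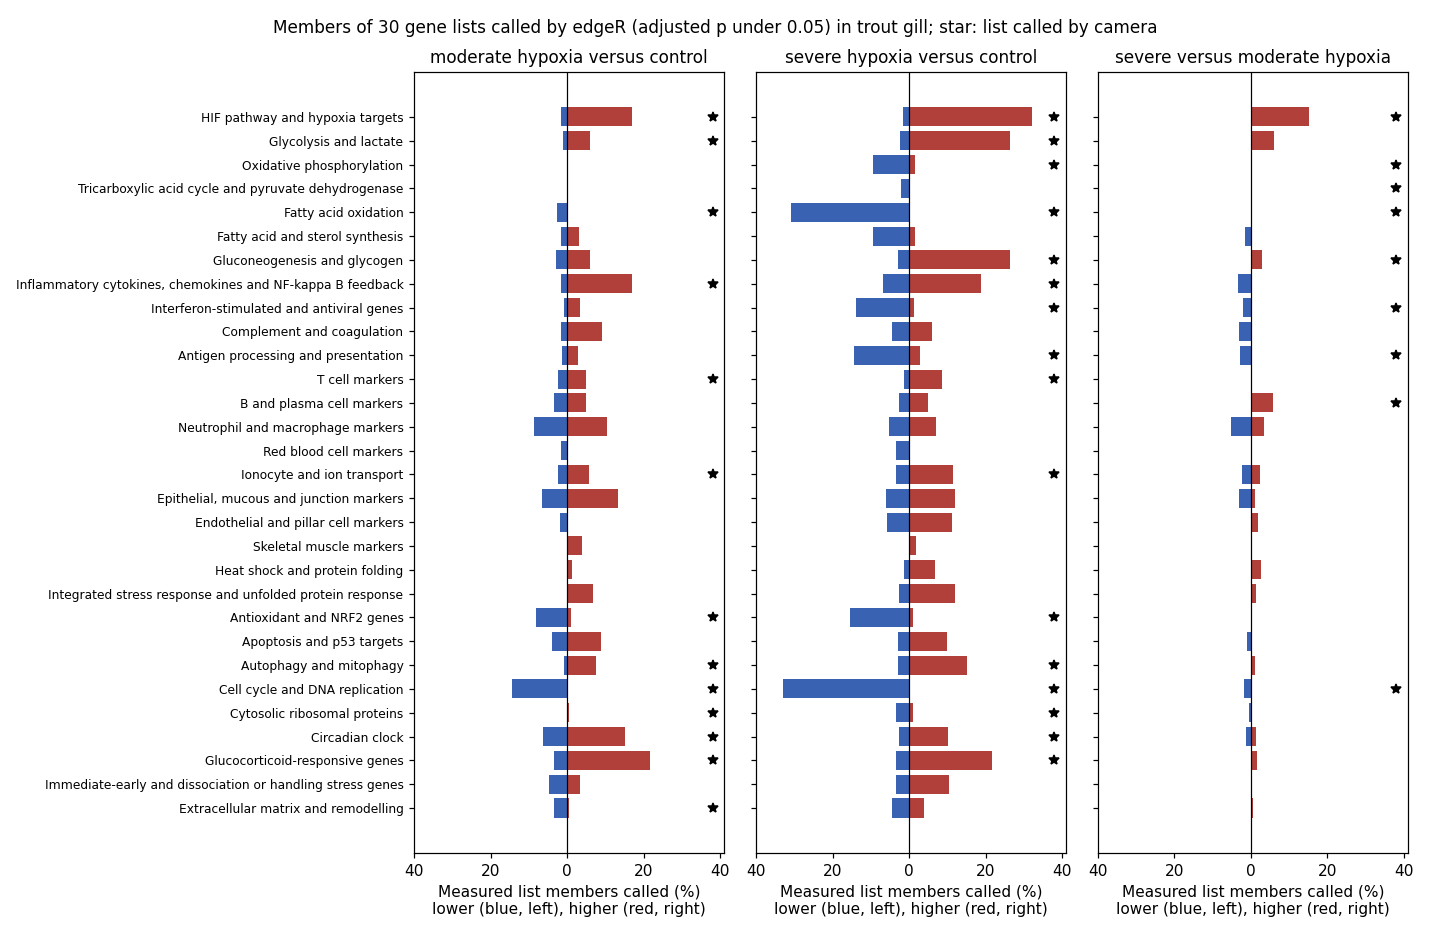
Percent of the measured members of each of the 30 lists that edgeR called higher (red, right) or lower (blue, left) in the 3 comparisons, with a star where camera called the list. Stars mark 13, 16 and 9 lists, among them the tricarboxylic acid cycle in severe against moderate hypoxia, where 0 members passed.

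In severe hypoxia against control, camera with a preset correlation called 16 of 30 lists, among them HIF targets (higher) and cell cycle, fatty acid oxidation, oxidative phosphorylation and interferon-stimulated genes (lower). With an estimated correlation only the HIF list was called. Egln3 rose from 4.22 ± 1.24 to 34.7 ± 2.36 CPM (SD, n = 3), ero1a from 8.88 ± 0.975 to 51.3 ± 6.32 CPM and ddit4 (110530482), an inhibitor of the growth kinase mTOR, from 0.807 ± 0.177 to 6.78 ± 0.815 CPM. The licensing factor mcm3 (110529168) fell from 45.5 ± 1.23 to 21.8 ± 1.67 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2792 of 30581 genes passed, 1482 higher and 1310 lower. Of these, 538 changed at least 2-fold in the estimate (332 higher, 206 lower), and 65 passed a test against a 2-fold change (58 higher, 7 lower). With upper quartile scaling 1298 genes were called higher and 1551 lower. The values did not overlap for 8767 genes (28.7%), where chance gives 10%.

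The HIF list rose (camera adjusted p = 7.1e-10), a call that also held with an estimated correlation (adjusted p = 0.024). Of 59 members 19 rose and 1 fell, ANGPTL4 again, or 25 and 2 adjusted over the list alone. The hif1a copies 100135944 and 110505629 rose by 0.59 ± 0.10 and 1.03 ± 0.11 on the log2 scale (SE), and VEGFA stood at 15.7 ± 3.06 CPM (edgeR adjusted p = 0.29). Glycolysis genes rose (camera adjusted p = 0.003; adjusted p = 0.13 with an estimated correlation), 22 of 83 higher and 2 lower, or 24 and 3 adjusted over the list alone. The glucose transporter Slc2a1 (110494474) rose from 71.7 ± 3.15 to 132 ± 7.36 CPM and pgam1b by 1.07 ± 0.12, and the members that fell were pyruvate dehydrogenase kinases, pdk2a (110491496) and Pdk2 (110538080). Gluconeogenesis and glycogen genes rose (camera adjusted p = 0.0068; adjusted p = 0.19 with an estimated correlation), 9 of 34 higher and 1 lower, or 13 and 1 adjusted over the list alone. Members that rose included genes that act on glycogen, ppp1r3cb (110491403), a glycogen-targeting phosphatase subunit, at 1.02 ± 0.09 and glycogenin GYG1 (110527394) at 1.00 ± 0.11, whereas the gluconeogenic FBP1 (100136618) fell in 14 of 19 settings.

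Of the metabolic lists, oxidative phosphorylation and fatty acid oxidation were called lower. In the oxidative phosphorylation list (camera adjusted p = 5e-06; adjusted p = 0.31 with an estimated correlation), 18 of 191 members fell, 3 rose and 170 did not pass, or 19 and 3 adjusted over the list alone. The complex I subunit ndufc2 (100305333) fell by 0.49 on the log2 scale, while a gene described as cytochrome c oxidase subunit 4 isoform 2 (symbol COX4I1, 110535290) rose from 50.1 ± 9.76 to 106 ± 20.6 CPM. Fatty acid oxidation genes fell (camera adjusted p = 3.6e-06; adjusted p = 0.19 with an estimated correlation), 12 of 39 lower and 0 higher, or 14 and 0 adjusted over the list alone, among them HADH at -0.66 ± 0.11 and the acylcarnitine carrier slc25a20 (110494978) at -0.55 ± 0.10. In the fatty acid and sterol synthesis list 6 of 64 fell and 1 rose (camera adjusted p = 0.086), among them cyp51 (110496341) of cholesterol synthesis at -0.99 ± 0.17. The tricarboxylic acid cycle list had 1 member lower of 48 (camera adjusted p = 0.69). Antioxidant genes fell (camera adjusted p = 0.0028; adjusted p = 0.19 with an estimated correlation), 15 of 97 lower and 1 higher, or 19 and 3 adjusted over the list alone, with MGST1 at -0.74 ± 0.11. Autophagy genes rose (camera adjusted p = 6e-05; adjusted p = 0.13 with an estimated correlation), 16 members higher, 3 lower and 86 not past the test, or 21 and 3 adjusted over the list alone, with sqstm1 at 0.64 ± 0.10 and the initiating kinase ULK2 (110507875) at 0.87 ± 0.15.

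Cell cycle and DNA replication genes fell (camera adjusted p = 1e-15; adjusted p = 0.17 with an estimated correlation). Of 112 members 37 fell and 0 rose, or 44 and 1 adjusted over the list alone. Besides mcm3, uhrf1 (110533997), which maintains DNA methylation at replication, fell from 27.8 ± 0.74 to 13.5 ± 0.883 CPM. Ribosomal proteins fell by a median of 0.10 on the log2 scale (camera adjusted p = 0.003; adjusted p = 0.74 with an estimated correlation), 7 of 212 lower and 2 higher, or 5 and 2 adjusted over the list alone. The members that rose were the kinases RPS6KA3 and rps6ka1 (110505267, in 15 of 19 settings), which are not ribosomal proteins, and rpl5a (110530101) fell by 0.69. The ribosomal call was lost without control replicate 3 or severe replicate 2 (camera adjusted p = 0.15 for each), without the library of largest hemoglobin share in each group (0.96) and with fry (0.23). Glucocorticoid-responsive genes rose (camera adjusted p = 6e-05; adjusted p = 0.13 with an estimated correlation), 13 of 60 higher and 2 lower, or 18 and 3 adjusted over the list alone, with fkbp5 at 2.14 ± 0.19 and hsd11b2 (100135822) at -2.21 ± 0.39. Clock genes rose (camera adjusted p = 0.04; adjusted p = 0.25 with an estimated correlation), 8 of 79 higher and 2 lower, or 12 and 3 adjusted over the list alone, with nr1d2b (110496425) at 1.01 ± 0.12 and Tef at 0.96 ± 0.14. That call was lost without control replicate 2 (camera adjusted p = 0.097), severe replicate 2 (0.077) or the library of largest hemoglobin share in each group (0.05).

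Immune lists moved in different directions in severe hypoxia. Inflammatory genes rose (camera adjusted p = 0.017; adjusted p = 0.13 with an estimated correlation), 33 of 176 higher and 12 lower, or 38 and 15 adjusted over the list alone. The gene il1b rose to 23.6 ± 5.51 CPM, and the NF-kappa B feedback genes Tnfaip3 (100136337) and NFKBIA (100136058) rose by 1.44 ± 0.11 and 0.88 ± 0.09. Without control replicate 3 the list was not called (camera adjusted p = 0.051). Interferon-stimulated genes fell (camera adjusted p = 0.003; adjusted p = 0.43 with an estimated correlation), 20 of 144 lower and 2 higher, or 22 and 5 adjusted over the list alone. That call was lost without severe replicate 3 (camera adjusted p = 0.1). The guanylate-binding GTPase GBP1 (110501732) fell from 47.9 ± 1.15 to 22.6 ± 4.2 CPM and the transcription factor Irf1 (110499402) from 43.5 ± 10.7 to 19.3 ± 4.32 CPM. A member that rose, Trim25 (110500408), is described in the files as trim47, another ubiquitin ligase. Antigen presentation genes fell (camera adjusted p = 0.015; adjusted p = 0.3 with an estimated correlation), 10 of 69 lower and 2 higher, or 15 and 4 adjusted over the list alone. The call was lost without control replicate 3 (camera adjusted p = 0.12), severe replicate 2 (0.053) or the library of largest hemoglobin share in each group (0.39). The peptide transporter Tap2 (110488345) fell by 0.68, while the lysosomal reductase ifi30 (110508906) rose by 0.55 ± 0.09. T cell markers rose (camera adjusted p = 0.035; adjusted p = 0.3 with an estimated correlation), 7 of 81 higher and 1 lower by both adjustments, over all genes and adjusted over the list alone. The T cell call was lost without control replicate 1 (camera adjusted p = 0.18) or severe replicate 1 (0.17).

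Ionocyte genes rose in severe hypoxia (camera adjusted p = 0.015; adjusted p = 0.23 with an estimated correlation), 10 of 88 higher and 3 lower, or 14 and 5 adjusted over the list alone, with 2 carbonic anhydrase 4 genes at 1.26 ± 0.10 (CA12) and 1.47 ± 0.13 (CA4, 110530653). The ionocyte call was lost without control replicate 2 (camera adjusted p = 0.058) or severe replicate 1 (0.068). The mucin-5ac-like genes 118940990 and 118940991 rose by 4.04 ± 0.28 and 3.78 ± 0.25, and a mucin-2-like gene (118941172) went from 0.127 ± 0.219 to 3.1 ± 1.18 CPM, with 5 counts over the control group. Among genes of the heat shock list, which was not called (camera adjusted p = 0.28), 5 of 75 rose and 1 fell, with hsp90a.1 (110529844) at 1.49 ± 0.17. In the integrated stress response list (camera adjusted p = 0.18) 9 of 75 rose and 2 fell, with the cystine transporter Slc7a11 (110487732) at 1.24 ± 0.14 and the serine synthesis enzyme PHGDH (110520091) at -0.80 ± 0.14. Leaving out a control library moved the count of 2792 calls by over 1.5 times, to 1664, 1704 and 1582 without control replicates 1, 2 and 3. Without the library of largest hemoglobin share in each group 1225 genes were called.

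Severe and moderate hypoxia, sampled at the same time, differed in some hypoxia targets and immunoglobulin loci. Of 59 measured HIF list members 9 were higher in severe hypoxia, and of 101 measured immunoglobulin loci 18 were higher and 0 lower. Camera with a preset correlation called 9 of 30 lists, and with an estimated correlation only the HIF list. Egln3 stood at 34.7 ± 2.36 CPM in severe and 14.5 ± 0.734 CPM in moderate hypoxia (SD, n = 3), and ankrd37 (110534293), a HIF target, at 40.3 ± 3.19 and 18.3 ± 1.82 CPM. The C-C motif chemokine 19 gene (110536449) was lower in severe hypoxia, at 44.3 ± 7.11 against 112 ± 8.75 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 262 of 30581 genes passed, 110 higher and 152 lower in severe hypoxia. Of these, 87 changed at least 2-fold in the estimate (47 higher, 40 lower), and edgeR's test against a 2-fold change called 0 genes, with 153 at an unadjusted p under 0.05. The values did not overlap for 5812 genes (19%), where chance gives 10%.

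The HIF list was higher in severe than in moderate hypoxia (camera adjusted p = 5e-09; adjusted p = 0.028 with an estimated correlation), 9 of 59 members higher and 0 lower, or 19 and 0 adjusted over the list alone. The hif1a copies 100135944 and 110505629 did not pass, at 0.15 ± 0.10 and 0.35 ± 0.11 on the log2 scale (SE; edgeR adjusted p = 0.57 and 0.15). Gluconeogenesis and glycogen genes were higher (camera adjusted p = 0.00038; adjusted p = 0.18 with an estimated correlation), with 1 of 34 past the test, ppp1r3cb (110491403) at 0.63 ± 0.09, or 6 adjusted over the list alone. In the glycolysis list 5 of 83 were higher (17 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.096), among them Slc2a1 at 0.62 ± 0.09. Oxidative phosphorylation (camera adjusted p = 2.7e-06; adjusted p = 0.51 with an estimated correlation) and fatty acid oxidation (camera adjusted p = 0.00096; adjusted p = 0.51 with an estimated correlation) were lower as lists, with medians of -0.125 and -0.12, with 0 members past the edgeR test over all genes and 0 and 9 lower adjusted over the list alone. The tricarboxylic acid cycle list was lower (camera adjusted p = 0.042; adjusted p = 0.57 with an estimated correlation) with 0 of 48 members past either adjustment. That call was lost without control replicate 3 (0.053), moderate replicates 1 (0.15) or 3 (0.11), or severe replicates 1 (0.18) or 3 (0.058), each a camera adjusted p. With membership by symbol alone it was lost as well (camera adjusted p = 0.058).

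Interferon-stimulated genes were lower in severe hypoxia (camera adjusted p = 1.1e-06; adjusted p = 0.37 with an estimated correlation) by a median of -0.25, with 3 of 144 past the test and lower, the same count adjusted over the list alone. They included irf1a (110502724) at -1.96 ± 0.35 and GBP1 at -0.71 ± 0.14, whose calls held in 16 and 15 of 19 settings. Antigen presentation genes were lower (camera adjusted p = 6.1e-06; adjusted p = 0.18 with an estimated correlation) by a median of -0.26, with 2 of 69 lower, or 14 adjusted over the list alone. These were ifi30 at -0.55 ± 0.09 and beta-2-microglobulin b2m (110491889), the light chain of class I molecules, at 1190 ± 111 against 2240 ± 375 CPM in 14 of 19 settings. In the inflammatory list 6 of 176 were lower (2 higher and 15 lower adjusted over the list alone; camera adjusted p = 0.096), among them a CCL4 gene (110530730) at -1.15 ± 0.17, while il1b differed by 0.11 ± 0.22 (edgeR adjusted p = 0.88). CYBB (110504932) was lower in severe hypoxia, at 358 ± 73.3 against 613 ± 107 CPM in 11 of 19 settings. Another CYBB copy (118936247) was higher, at 173 ± 14.6 against 126 ± 5.83 CPM in 10 of 19 settings. MPO was higher, at 1390 ± 144 against 948 ± 74.4 CPM in 14 of 19. The secreted mucins mucin-5ac (110534375) and mucin-2 (110518543) were lower, at 340 ± 38 against 700 ± 47.3 and 92.4 ± 12.7 against 160 ± 22.6 CPM, whereas the mucin-5ac-like gene 118940991 was higher, at 15.5 ± 2.91 against 7.86 ± 1.61 CPM in 13 of 19.

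The B and plasma cell list was higher in severe hypoxia (camera adjusted p = 0.011; adjusted p = 0.18 with an estimated correlation), with 7 of 120 members higher and 0 lower, or 13 and 2 adjusted over the list alone. All 7 were immunoglobulin loci, such as IGKV4-1 (22607) at 17.9 ± 1.67 against 8.27 ± 1.39 CPM and K-BAS (22671) at 86.8 ± 20.6 against 44.6 ± 6.76 CPM. They are assembled loci of a multigene family whose near-identical copies can share reads, so the value of a single locus is uncertain. The list was not called without moderate replicate 2 (camera adjusted p = 0.058), without the library of largest hemoglobin share in each group (0.11) or with membership by symbol alone (0.32). Cell cycle genes were lower (camera adjusted p = 0.00055; adjusted p = 0.57 with an estimated correlation), with mcm3 at -0.53 ± 0.10 and uhrf1 at -0.56 ± 0.11 (in 13 and 12 of 19 settings), the 2 of 112 that passed, or 7 adjusted over the list alone. The cell cycle list was not called without severe replicate 2 (camera adjusted p = 0.26) or without the library of largest hemoglobin share in each group (0.1). In the ionocyte list 2 of 88 were higher and 2 lower (camera adjusted p = 0.74), among them the chloride channel cftr (110499460) at 0.63 ± 0.13, in 10 of 19 settings, and the potassium channel kcnj1a.1 (110507858) at -1.36 ± 0.22. The count of 262 calls moved by over 1.5 times without moderate replicates 1 (124), 2 (113) or 3 (112) or severe replicate 1 (145), with only these groups in the fit (129), without a filter (408) and with DESeq2 (754). Without the library of largest hemoglobin share in each group 105 genes were called.

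**Figure D2:**
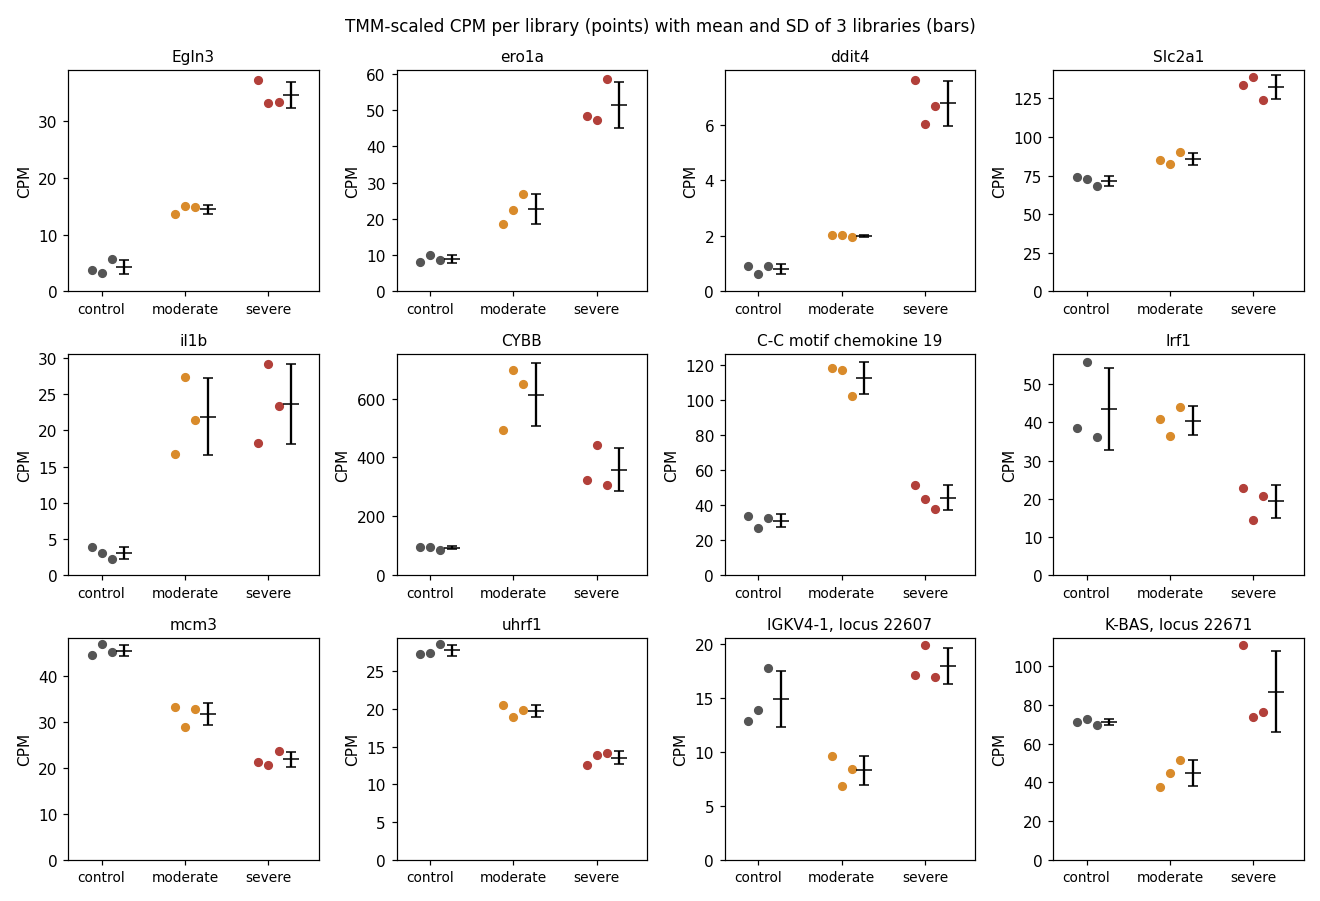
Normalised CPM of 12 genes in each library (points, 3 per group) with the mean and SD of each group (bar at its right). Egln3 rose from a mean of 4.22 CPM in the control to 14.5 in moderate and 34.7 in severe hypoxia, and the locus IGKV4-1 (22607) stood at 14.9, 8.27 and 17.9 CPM.

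Markers of other cell types gave no call for red blood cells, endothelium or skeletal muscle. Red blood cell genes had 1 of 60 members lower in moderate and 2 lower in severe hypoxia (camera adjusted p = 0.68 and 0.54), with medians of -0.05 and -0.01 on the log2 scale, and alas2 (110532218) of heme synthesis did not pass in either (edgeR adjusted p = 0.97 and 0.83). Endothelial markers had 1 of 53 lower in moderate hypoxia (camera adjusted p = 0.068), and 6 higher and 3 lower in severe hypoxia (0.58), with EDNRA (110534525), described as endothelin receptor type B, at 0.85 ± 0.11. Muscle markers had 2 and 1 of 53 members higher (camera adjusted p = 0.99 and 0.81). Against the control, B and plasma cell markers had 6 of 120 higher and 4 lower in moderate (camera adjusted p = 0.3) and 6 higher and 3 lower in severe hypoxia (0.11), with PRDM1 (110522002), a regulator of plasma cell differentiation, at 2.39 ± 0.34 and 2.41 ± 0.34. Myeloid markers had 4 of 57 higher and 3 lower in severe hypoxia (camera adjusted p = 0.58), and epithelial markers 20 of 167 higher and 10 lower (0.45).

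Among the remaining lists, complement and coagulation genes had 6 of 66 higher and 1 lower in moderate and 4 higher and 3 lower in severe hypoxia (camera adjusted p = 0.65 and 0.69), with tissue factor F3 (110489539), which starts coagulation, at 16.3 ± 0.682 and 14.1 ± 0.387 against 6.13 ± 0.967 CPM. Apoptosis and p53 targets had 9 of 102 higher and 4 lower in moderate and 10 higher and 3 lower in severe hypoxia (camera adjusted p = 0.094 and 0.54), with cytochrome c (cyc, 110520139), which also carries electrons in respiration, among the higher members at 90.3 ± 5.16 and 78.3 ± 12 against 45.2 ± 5.81 CPM. Immediate-early and handling genes had 3 of 86 higher and 4 lower in moderate and 9 higher and 3 lower in severe hypoxia (camera adjusted p = 0.15 and 0.27), and extracellular matrix genes 9 of 226 higher and 10 lower in severe hypoxia (0.11). In moderate hypoxia the lists of interferon-stimulated genes (5 of 144 higher, 1 lower), antigen presentation (2 of 69 higher, 1 lower), integrated stress response (5 of 75 higher), heat shock (1 of 75 higher, with hsp70 at an edgeR adjusted p of 0.54), oxidative phosphorylation and tricarboxylic acid cycle (0 members each), fatty acid and sterol synthesis (2 of 64 higher, 1 lower) and gluconeogenesis and glycogen (2 of 34 higher, 1 lower) were not called. Their camera adjusted p ran from 0.12 to 0.65. In severe against moderate hypoxia the 21 lists not called had a camera adjusted p of 0.085 or more. Median, mean and test differed in sign for muscle, heat shock and gluconeogenesis in moderate hypoxia, muscle in severe hypoxia, and red blood cell, muscle, antioxidant, clock, glucocorticoid and immediate-early genes in severe against moderate hypoxia, none of them called.

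The responses to moderate and severe hypoxia were compared over all 30581 genes. Of the calls against the control, 647 genes were higher in both hypoxia groups and 296 lower in both, where independent lists would share 48.5 and 22.1. In 20 simulations all 9 libraries, the controls included, were drawn gene by gene from a mean per gene common to the 3 groups. At most 2 genes were then called in both in the same direction. The simulated comparisons shared their controls, but held no deviation of the real controls common to many genes. The covariance of the log2 fold changes across genes was 0.1496, against 0.0538 in these simulations (0.0509 to 0.0582), a difference of 0.096. Pearson's r was 0.658 against 0.5 simulated. Genes are not independent replicates, and both comparisons used the same 3 control libraries. The 3 genes called in opposite directions, named after their values were seen, were a secreted immunoglobulin mu heavy chain locus (18757), LITAF (110486939) and TFPI2 (110488022). The heavy chain locus stood at 745 ± 26.6 CPM in the control, 410 ± 59.4 in moderate and 1200 ± 80.5 in severe hypoxia. TFPI2, an inhibitor of coagulation, stood at 21.4 ± 2.48, 38.9 ± 4.08 and 14.6 ± 2 CPM, its fall in severe hypoxia called in 14 of 19 settings, and LITAF at 88.9 ± 11.2, 122 ± 4.58 and 69.2 ± 2.05 CPM.

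The authors' deposited table of called genes held 487 genes for moderate hypoxia against control (311 higher, 176 lower), of which 380 were among the calls here. The authors' deposited table held 576 genes for severe hypoxia against control (373 higher, 203 lower), of which 492 were among the calls here. For severe against moderate hypoxia the authors' deposited table held 158 genes (98 higher, 60 lower), of which 88 were among the calls here. No shared gene had the opposite sign in the authors' deposited table. The authors' called genes had an absolute log2 fold change of at least 1.001, 1.002 and 1.005, whereas the calls here had no fold cut. Of the calls here that changed at least 2-fold, 370 of 401, 482 of 538 and 85 of 87 were among the authors' called genes.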

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

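The tests of leukocyte share, single libraries, B cell share and shared reads were chosen only after the results were seen; the tests of time of day, blood content and other splits were planned. Severe and moderate hypoxia differed by the edgeR quasi-likelihood test of the difference itself in 262 genes, and by camera with a preset correlation in 9 lists. With an estimated correlation 8 of the 9 calls were lost, all but that of HIF targets. The list medians, severe minus moderate on the log2 scale, were 0.274 for HIF targets, 0.261 for gluconeogenesis and glycogen, 0.085 for B and plasma cell markers, -0.125 for oxidative phosphorylation, -0.105 for the tricarboxylic acid cycle, -0.12 for fatty acid oxidation, -0.246 for interferon-stimulated genes, -0.26 for antigen presentation and -0.157 for cell cycle.

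The genes named in a comparison with the control that also passed this edgeR test are given as severe minus moderate on the log2 scale. Higher in severe hypoxia were ddit4 at 1.757, Egln3 (110505778) at 1.259, ero1a at 1.178, Slc2a1 at 0.623, ppp1r3cb at 0.633, the heat shock genes hsp90a.1 at 1.087 (110529844) and 1.242 (110522488), cyp1c3 (100462685) at 2.895, the mucin-5ac-like gene 118940991 at 0.977, krt13 (110495128) at 0.601, EDNRA (110534525) at 0.495, MPO at 0.55 and CCN1 (110535861) at 0.724. RTN4RL2 (110488837) differed by 3.66, at 5 counts in the moderate group and 72 in the severe group. The immunoglobulin loci IGKV4-1 (22607) and K-BAS (30094) were higher by 1.115 and 0.829. Both loci, cyp1c3, krt13 and MPO were called lower in moderate hypoxia than in the control. In severe hypoxia against the control they did not pass (edgeR adjusted p = 0.32, 0.72, 0.72, 0.82 and 0.68). Lower in severe hypoxia were the C-C motif chemokine 19 gene 110536449 at -1.345, TFPI2 at -1.421, kcnj1a.1 at -1.36, Irf1 (110499402) at -1.067, CYBB (110504932) at -0.775, GBP1 at -0.705, NR1D2 (110515629) at -0.693, uhrf1 at -0.555, ifi30 at -0.546, mcm3 at -0.534 and rpl5a at -0.473.

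Genes called in both hypoxia groups against the control were weighed against time of day and blood content. Red blood cell genes argued against blood content, with list medians of -0.052 and -0.007 on the log2 scale; of the 60 measured members 6 are also in another list. Control gills were sampled at 0 h and hypoxia gills at 12 h, and 21.5% and 12.7% of the 79 measured clock members were called, beside 1515 and 2792 of 30581 over all genes; the clock list was called in both comparisons, but in neither with an estimated correlation (adjusted p = 0.19 and 0.25). A change with time of day may account for part of the calls and stays open, as does hypoxia itself. The real splits gave 1515, 2792 and 262 calls and the highest of the other splits 1, 2 and 3, but the 10 splits of 6 libraries cannot give a share under 0.05.

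The lower interferon-stimulated and antigen presentation lists in severe against moderate hypoxia were weighed against a lower share of leukocytes and a single library. A lower share of all leukocytes was taken to need T cell, B cell and myeloid medians at or below -0.123. That is the midpoint between 0 and the interferon median, a cut chosen after the results were seen. The highest median, 0.085, was that of the B cell list, whose called members were all immunoglobulin loci. Its 88 other members had a median of 0.016 (interval -0.049 to 0.091). That argues against a fall to the cut in these members. The T cell and myeloid intervals, -0.18 to 0.021 and -0.178 to -0.006, both include the cut. A lower share of all leukocytes is therefore not excluded. Fewer T cells or myeloid cells alone, with medians of -0.042 and -0.08, stay open; 3 of 81 T cell, 4 of 120 B cell and 2 of 57 myeloid members are also in another list. No single library carried the calls, since the highest camera adjusted p of both lists was 0.003 with each library left out, although with an estimated correlation neither list was called (adjusted p = 0.37 and 0.18), nor the interferon list with fry (0.11). The lower oxygen level may lower these transcripts. No test here separates this hypothesis from a change in 1 cell type, a lower share of leukocytes or a difference between tanks.

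The immunoglobulin loci higher in severe than in moderate hypoxia were weighed against a larger share of B cells and against reads shared by near-identical copies. Of 101 measured loci 18 were higher and 0 lower. The median on the log2 scale was 1.298 over the 18 called loci and 1.091 over all 101. Of the 18, 9 were lower in moderate hypoxia than in the control, while 4 were higher in severe hypoxia than in the control. The 88 B cell members that are not immunoglobulin loci had a median of 0.016 (95% interval -0.049 to 0.091), and 0 of them were called higher. That median lies under 0.649, the midpoint between 0 and the median of the called loci, a cut chosen after the results were seen. The values argue against a rise of that size in these 88 members as a set. In bulk tissue other cells may express some of them, so a larger share of B cells is not excluded. The fold changes of the called loci differed beyond their standard errors (chi-square heterogeneity p = 1.1e-10). The called loci include heavy and light chain genes, however, which need not share a fold change. The test therefore cannot decide whether near-identical copies share reads. Sharing of reads, and a change in plasma cells or in immunoglobulin transcripts per cell, may account for the pattern. These stay open, as does a larger share of B cells.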

How the results depend on the processing

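The setting without the library of largest hemoglobin share in each group and the setting without kinases in the ribosomal protein list were chosen after the data were seen; the others were planned. The hemoglobin setting gave 730, 1225 and 105 calls for moderate hypoxia against control, severe hypoxia against control and severe against moderate hypoxia, where fewer libraries entered the fit. With 1 library left out, calls ranged from 849 to 2112, 1582 to 2553 and 112 to 370. Counts moved by over 1.5 times without control replicates 1, 2 and 3 (849, 935 and 934 calls in moderate and 1664, 1704 and 1582 in severe hypoxia), without moderate replicate 1 (930) or 3 (957), and in severe against moderate hypoxia without moderate replicates 1 to 3 (124, 113 and 112) or severe replicate 1 (145). For severe against moderate hypoxia 408 genes were called without a filter, 754 with DESeq2 and 129 with only these groups in the fit; the cause was not tested. Upper quartile scaling moved the share of higher calls from 66% to 58.4% in moderate and from 53.1% to 45.6% in severe hypoxia against control. The covariance of both responses was 0.0948 over genes of at least 10 CPM, against 0.0173 in simulations of unchanged groups, and 0.1496 over all genes, against 0.0538. Of the named called genes 48 of 91, 80 of 112 and 9 of 38 were called in every setting, and 0 changed sign. Of 13, 16 and 9 called lists, 12, 15 and 8 were lost with an estimated correlation and 3, 3 and 5 with fry. In the other settings where lists were retested, 11, 9 and 6 held throughout. Those were DESeq2 size factors, the replicate block, each library left out, symbol membership and the hemoglobin setting. For ribosomal proteins the list without kinases was added. Lists were not retested with upper quartile scaling, other filters, hemoglobin genes removed or only the groups compared. The fry losses, as adjusted p, were fatty acid oxidation (0.11), ribosomal proteins (0.15) and extracellular matrix (0.32) in moderate hypoxia, and interferon-stimulated genes (0.11), T cell markers (0.072) and ribosomal proteins (0.23) in severe hypoxia. In severe against moderate hypoxia they were oxidative phosphorylation, fatty acid oxidation and interferon-stimulated genes (0.11 each), and the tricarboxylic acid cycle and cell cycle (0.26 each).

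The labels do not say that replicate numbers pair libraries, so the main fit held no block. Same-numbered libraries also did not deviate together in a later check. Correlations of same-numbered libraries ran from -0.071 to 0.046 over 9 pairs, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block 1257, 2265 and 191 genes were called, of which 1185, 2183 and 165 were among the calls without it, and the tricarboxylic acid cycle list was not called (camera adjusted p = 0.066).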

Other observations

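The pathway tests and genes given here were chosen only after the results were seen. Among genes called higher in moderate hypoxia, 15 pathways were over-represented by the one-sided Fisher's exact test with Benjamini-Hochberg adjustment. That test takes genes as independent, which correlated genes and paralogs are not, so its p-values may be too small. Pathways also share genes, such as B4galt1 (110497417) in galactose metabolism and keratan sulfate synthesis, so they are not separate results. Cytokine-cytokine receptor interaction came first, with 45 of 376 measured genes (adjusted p = 1.2e-10), and pathways of glycan synthesis were also among the 15. Galactose metabolism held 8 of 38 measured genes where 1.4 were expected (adjusted p = 0.0012), with a galactosyltransferase B4galt1 (110497417) at 0.71 ± 0.09 on the log2 scale. Among genes called higher in severe hypoxia 12 pathways passed, with glycolysis and gluconeogenesis first (20 of 100, adjusted p = 1.6e-05). Severe hypoxia also gave 10 of the 38 galactose metabolism genes (0.00039) and 7 of 32 genes of keratan sulfate synthesis (0.017). In moderate hypoxia keratan sulfate synthesis held 6 of 32 (adjusted p = 0.013), among them the sialyltransferase ST3GAL1 (110488197), which rose by 2.78 ± 0.19 in moderate and 3.38 ± 0.20 in severe hypoxia. Drug metabolism by cytochrome P450 held 9 of 50 genes called lower in moderate hypoxia (adjusted p = 2.3e-05), with the glucuronosyltransferases ugt3 (110501343) at -1.74 ± 0.16 and ugt3 (118943577) at -2.03 ± 0.20.

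In severe hypoxia, the same Fisher's exact test, with the same limits, called 18 pathways among genes called lower. The related cell cycle list was not called by camera with an estimated correlation (adjusted p = 0.17). DNA replication held 27 of 52 measured genes (adjusted p = 2e-19), mismatch repair 15 of 32 (8.9e-10), ribosome biogenesis 24 of 123 (7.3e-07), the spliceosome 33 of 276 (0.00014) and the proteasome 18 of 109 (0.00027). Metabolic pathways were also among the 18, such as glutathione metabolism with 14 of 87 (0.0026) and fatty acid degradation with 11 of 68 (0.01). Outside the lists, Acod1 (110515535), which makes itaconate in activated macrophages, rose by 2.53 ± 0.12 in moderate and 1.80 ± 0.12 in severe hypoxia. The synthase alas1 (110528663) of heme synthesis rose by 1.51 ± 0.10 and 1.37 ± 0.10, and the transporter ABCG2 (110534550) fell by 1.93 and 2.02 on the log2 scale. The histone deacetylase HDAC4 (110528724) rose by 2.39 ± 0.16 and 3.42 ± 0.17. The gene fih1 (101268916), which inhibits HIF by hydroxylation, rose by 1.31 ± 0.12 in moderate and 2.18 ± 0.12 in severe hypoxia and was higher there than in moderate hypoxia by 0.87 ± 0.11.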
